A study of Homo sapiens with 9 samples.

How the data were processed

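Total RNA from 9 samples of SUIT2, a human pancreatic cancer cell line, was sequenced on an Illumina HiSeq 3000 after extraction with a column kit, per the labels' protocols. Cells had been seeded at 500000 per well of a 6-well plate and received fresh medium with interferon beta at 100 U/mL for 6 or 24 h. The labels give the same protocol text on the control samples and no time for them. Per the submitters' processing notes STAR 2.7.8a, Partek and the hg38 build were used. The annotation release, the counting settings and the strand setting are not given in the sources used here.

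The authors deposited a table of estimated counts per gene for 59609 genes, whose values need not be whole. The design fixed before the data were examined assumed counts, so the estimated counts were rounded to whole numbers first. The authors also deposited a TMM-normalized signal table, in which 0.0001 had been added to each count and each library had 1 multiplier, as checked against the first table. Groups and replicate numbers came from the sample titles. Coordinates are those of the deposited tables on hg38, 1-based; for 81.6% of symbols shared with the reference annotation used here the start was the same, and for 81.6% the end was 1 base further. Genes that overlap others cannot be told apart without the strand setting. Overlaps are given below for some of the named genes only.

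Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), by the quasi-likelihood test with TMM factors, in 1 model over all 9 libraries with 6 residual degrees of freedom. The filter took a minimum count of 10 and a minimum total of 15, which left 16964 genes, and 0.05 was the threshold on the Benjamini-Hochberg adjusted p. The biological coefficient of variation was 0.0392. Standard errors are of log2 fold changes, taken as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. For large changes from a few counts in a group such a value can understate the error. Levels are CPM with TMM factors, as mean ± SD. The comparisons were 6 h against control, 24 h against control and 24 h against 6 h.

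Fixed before the data were examined, 31 gene lists held 706 genes, all in the tables, and 28 with at least 5 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated one. The lists covered antiviral genes, interferon signalling, nucleic acid sensing, interferon genes, class I and class II antigen presentation, chemokines and cytokines, checkpoint ligands, thymidine and pyrimidine breakdown, deoxynucleotide synthesis, nucleoside transport, G1/S and replication, G2/M and mitosis, p53 targets, cell death, NF-kB targets, NAD and PARP, amino acid catabolism, cholesterol synthesis, glycolysis, hypoxia, ATF4 targets, immediate early genes, mitochondrially encoded genes, nuclear oxidative phosphorylation, ribosomal proteins, transition and matrix genes, ductal markers and housekeeping genes. Markers of leukocytes and of fibroblast, endothelial and acinar cells made up the others. Some genes stand on more than 1 list.

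Genes named in the text followed a rule fixed before the data were examined. It took the 10 largest rises and falls per comparison among genes with an adjusted p under 0.05, at least 5 CPM and groups that did not overlap, up to 4 called members per list, and the genes of the study question whatever their result. Not all of them are named, and some are not reported here. Among named genes that passed, the groups did not overlap for 60 of 60 at 6 h, 74 of 74 at 24 h and 77 of 77 between the times. For a gene not chosen by its result chance gives 10%. These genes were counted only if they passed the test, and the rule itself asks this of part of them. The lack of overlap is therefore no added support.

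Genes with 3 or fewer counts over a group are given as a ratio of summed counts with an exact 95% interval. Alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios scaling, library size only, other low-count filters, 2 groups per fit, a replicate block, each library left out, limma on log2 of the deposited normalized table with a pseudocount of 1 or 0.1, and a stricter threshold of 0.01. Thinning to the smallest total of 15101664 was added after the depths were seen. Simulated unchanged groups set against the same controls came from 50 simulations.

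The test was checked on simulated data with known changes, in 16306 genes. At 6 h it called 47.9% of genes changed 1.25-fold, 76.1% at 1.5-fold, 83.0% at 2-fold and 97.8% at 4-fold, and at 24 h 54.2%, 73.9%, 78.7% and 100%. No call had the wrong sign, and 10 and 8 calls fell among unchanged genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.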

Results

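RNA sequencing was used to measure gene expression in SUIT2, an established human pancreatic cancer cell line, with and without interferon beta, a type I interferon. The series asks which transcripts change after 6 or 24 h of exposure, and its title concerns interferon signalling driven by STING, metabolic change and imaging with FLT, a thymidine analogue used as a PET tracer. The 9 libraries formed 3 groups of 3: control, 100 U/mL for 6 h and 100 U/mL for 24 h. The labels give no duration for the control cultures. Estimated counts per library totalled 15101734 to 19632741 in control, 16799278 to 37420457 at 6 h and 25270387 to 40384407 at 24 h, so the treated libraries were on average deeper. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. All replicate pairs differed by more than sampling noise, with a mean chi-square per gene of 1.60 to 5.70 and a median of 0.59 to 1.41, and each library was counted as 1 sample. The first principal component held 41.5% of the variance and separated 6 h from control, and the second held 32.7% and separated 24 h from the other groups.

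The first comparison, 6 h against control, asks what changed early. Antiviral effector transcripts rose from low to high levels. RSAD2, which encodes the antiviral enzyme viperin (chromosome 2, 6865806 to 6898239), went from 1.11 ± 0.508 to 569.7 ± 12.5 CPM (TMM-normalized, mean ± SD, n = 3 per group), a 525-fold rise with a log2 fold change of 9.04 (SE 0.10). IFIT1, an RNA-binding inhibitor of viral translation (chromosome 10, 89392546 to 89406487), rose 222-fold to 1575 ± 35.3 CPM, and MX1, a GTPase that blocks virus replication, rose to 2019.8 ± 10.6 CPM with a log2 fold change of 7.34 (SE 0.089). ETV7, a transcriptional repressor of the ETS family, rose by 9.57 (SE 0.15) from control counts of 0, 2 and 2, TRIM22, a ubiquitin ligase with antiviral activity, rose by 9.47 (SE 0.11), and GBP4, a guanylate-binding protein, stood at 8.44 (SE 0.095). TRIM22 had control counts of 3, 4 and 2, and with so few counts the SEs of ETV7 and TRIM22 can understate the error. Among the genes that fell, CERK, the kinase that makes ceramide 1-phosphate (chromosome 22, 46684410 to 46738252), went from 115 ± 2.31 to 25.8 ± 0.203 CPM with a log2 fold change of -2.15 (SE 0.040), and ZMAT3, an RNA-binding p53 target, had -1.87 (SE 0.11). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 1.67e-18 for RSAD2, 1.64e-17 for IFIT1 and 5.02e-16 for CERK, each with all 3 libraries of one group above all 3 of the other. RSAD2 overlaps CMPK2, IFIT1 overlaps LIPA and TRIM22 overlaps TRIM5 on the annotation, and the strand setting of the counting is not given in the sources used here, so reads of overlapping genes could not be told apart.

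All 59 tested antiviral genes were higher at 6 h, with a median log2 fold change of 4.32 (8.12e-05 as the adjusted p of the camera test with an estimated correlation). Of interferon signalling genes, 15 were higher, 1 was lower and 5 did not pass. USP18, which removes ISG15 from proteins and restrains the receptor, rose by 6.26 (SE 0.047), and the transcription factors STAT2 and IRF9 rose by 3.96 (SE 0.060) and 2.99 (SE 0.065). The receptor chain IFNAR1 fell, with -0.20 (SE 0.043), and IFNAR2, the other chain, did not pass at 0.028 (SE 0.052). SOCS1, an inhibitor of JAK signalling, rose from 0.435 ± 0.190 to 6.60 ± 0.407 CPM. Sensors of nucleic acids numbered 17 higher, 2 lower and 0 not passed. The RNA helicases IFIH1 and DDX58 rose by 5.92 (SE 0.056) and 5.85 (SE 0.058). STING1, the adaptor named in the study's title (chromosome 5, 139475533 to 139482935), rose by 1.85 (SE 0.048), and CGAS, the DNA sensor that acts upstream of it, by 0.74 (SE 0.069). The gene of interferon beta itself, IFNB1, had at most 3 counts in any library and was not tested. Of the 9 interferon genes on the list of ligands, 1 was tested and did not pass at 6 h (it was higher adjusted over the list alone).

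Antigen presentation genes were also higher at 6 h. Of 22 class I genes, 21 were higher, 0 were lower and 1 did not pass, among them NLRC5, a transactivator of class I genes, at 5.47 (SE 0.061), the peptide transporter TAP1 at 4.03 (SE 0.038) and the heavy chain HLA-B at 3.81 (SE 0.039). Of 8 tested class II genes, 7 were higher, 0 were lower and 1 did not pass: their transactivator CIITA rose by 2.61 (SE 0.11) and the invariant chain CD74 by 1.71 (SE 0.052), whereas HLA-DMB, a peptide exchange factor, stood at 0.025 (SE 0.054). Of chemokine and cytokine genes, 7 were higher, 1 was lower and 4 did not pass. The chemokine CXCL10 had 3 counts over the control group and 168 over the 6 h group, a depth-adjusted ratio of 40.7 (95% counting interval 13.7 to 199), and CXCL11 had 2 and 80, a ratio of 29.03 (7.78 to 244). CSF1, the macrophage growth factor, rose by 3.63 (SE 0.084). Of checkpoint ligands, 8 were higher, 1 was lower and 1 did not pass (9 higher and 1 lower adjusted over the list alone). CD274, which encodes PD-L1, went from 0.179 ± 0.152 to 19.1 ± 1.66 CPM with a log2 fold change of 6.61 (SE 0.23), or 7.61 without control library 2. Its control counts were 2, 7 and 1, so its SEs against control can understate the error. LGALS9, a galectin, rose by 5.64 (SE 0.066), and NT5E, the surface enzyme that makes adenosine, by 0.57 (SE 0.034). IDO1, the first enzyme of tryptophan breakdown, had 1 control count and 363 at 6 h, a ratio of 263.5 (counting interval 47.0 to 10430). Intervals cover counting error only, and the fitted log2 fold changes of these genes moved with single libraries, to 6.00 for CXCL10 without control library 2 and 10.10 for IDO1 without control library 3.

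Cell death genes numbered 29 higher, 2 lower and 1 not passed, with XAF1, a pro-apoptotic antagonist of XIAP, at 6.21 (SE 0.095) and APOL6, an apolipoprotein linked to cell death, at 3.73 (SE 0.045). Of NAD and PARP genes, 16 were higher, 3 were lower and 10 did not pass (17 higher adjusted over the list alone), with the ADP-ribosyltransferase PARP14 at 3.95 (SE 0.042). Of amino acid catabolism genes, 4 were higher, 0 were lower and 5 did not pass (4 higher and 1 lower adjusted over the list alone). WARS1, the tryptophanyl tRNA synthetase, rose by 2.36 (SE 0.029). KMO, a kynurenine hydroxylase, had 1 control count and 51 at 6 h, a ratio of 37.0 (counting interval 6.35 to 1490), and its fitted log2 fold change moved to 7.26 without control library 3.

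The genes of thymidine and nucleotide metabolism bear on the tracer named in the title. TYMP, the phosphorylase that degrades thymidine (chromosome 22, 50525752 to 50530032), rose 22.2-fold from 7.05 ± 0.130 to 157 ± 7.32 CPM, a log2 fold change of 4.47 (SE 0.058). Of 13 tested genes of thymidine and pyrimidine breakdown, 7 were higher, 2 lower and 4 not passed, with a median of 0.12 that turned to -0.016 with library size only, a scaling under which the median of all genes was -0.145, against -0.005 with TMM. NT5C3A, a pyrimidine nucleotidase, rose by 3.00 (SE 0.054), and UPP1, a uridine phosphorylase, and CDA, cytidine deaminase, fell slightly, with -0.18 (SE 0.034) and -0.23 (SE 0.058). CMPK2, a mitochondrial nucleotide kinase, rose by 7.88 (SE 0.099) and SAMHD1, which hydrolyses deoxynucleotides, by 3.53 (SE 0.043), both of them also antiviral. Thymidine kinase TK1, which traps the tracer by phosphorylation (chromosome 17, 78174091 to 78187233), stood at 101 ± 2.19 in control and 105 ± 8.55 CPM at 6 h, a log2 fold change of 0.055 (SE 0.049) with adjusted p = 0.434 by edgeR. Without 6 h library 3 it was 0.128 and passed at adjusted p = 0.00764. The thymidylate synthase gene TYMS, at -0.01 (SE 0.028), DCK, deoxycytidine kinase, at -0.034 (SE 0.063), the ribonucleotide reductase subunit RRM2, at -0.021 (SE 0.026), and SLC29A1, the main equilibrative nucleoside transporter, at -0.081 (SE 0.052) did not pass, though each became lower and called with library size only. In the deposited normalized table they stood at 0.155, 0.109, 0.146 and 0.089, none of them called. DTYMK, thymidylate kinase, fell with -0.17 (SE 0.046), a call that ended without control library 1 (-0.127, adjusted p = 0.0699) and in the deposited table, where it stood at 0.001 (0.997). The transporters SLC29A2 and SLC29A3 fell with -0.39 (SE 0.063) and -0.50 (SE 0.15). The call of SLC29A3 was lost without control library 1 (-0.41, adjusted p = 0.0917), control library 3 (-0.423, 0.0824) or 6 h library 2 (-0.435, 0.0673), with DESeq2 (-0.505, 0.0607) or in the deposited normalized table (-0.246, 0.442). SCO2 and ODF3B overlap TYMP.

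**Figure D1:**
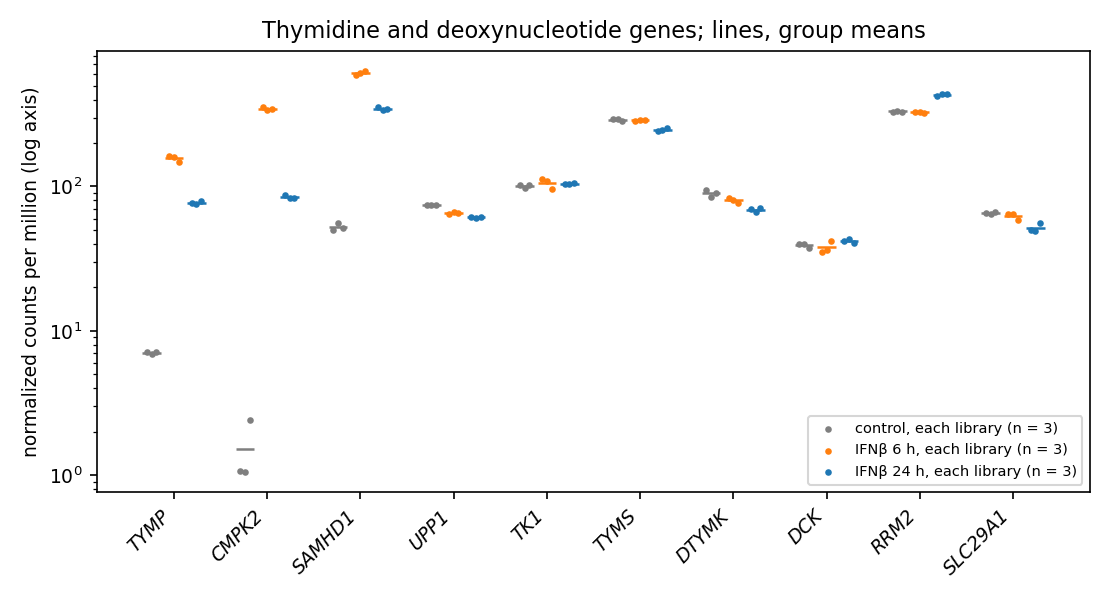
Normalized counts as CPM (log axis) of 10 thymidine and deoxynucleotide genes in each of the 9 libraries, with a line at each group's mean. TYMP, CMPK2 and SAMHD1 stand apart between the groups, from 7.05 to 157 and 77.1 CPM for TYMP, whereas TK1 stays between 101 and 105 CPM in the group means.

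By edgeR's test 5576 of 16964 genes passed at 6 h, 2968 higher and 2608 lower, of which 636 and 129 changed at least 2-fold and 4080 changed by under 1.5-fold. Of the calls 53.2% were higher, against 21.2% with library size only and 88.4% in the deposited normalized table, in which the median of all genes was 0.134. Of 28 lists tested with camera, 11 shifted, all of them up, and all 11 also passed with an estimated correlation. In mixed splits of the 6 libraries, in which 0 genes passed, camera called 5 to 11 lists. Each mixed split sets unequal numbers of treated and control libraries against each other. Part of the real difference remains in it, so these calls need not be false. The lists that shifted were antiviral genes, interferon signalling, nucleic acid sensing, both antigen presentation lists, chemokines, checkpoint ligands, thymidine breakdown, cell death, NAD and PARP, and amino acid catabolism. In the deposited table CDA, UPP1, SLC29A2, IFNAR1, INSIG1 and LYZ no longer passed at 6 h, and LYZ did not pass with library size only. TK1, IFNAR2, HLA-DMB and MKI67, none of them called at 6 h, turned to -0.084, -0.111, -0.114 and -0.116 with library size only, again without passing. Except where given, counts adjusted over the list alone were the same as over all genes.

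The other 17 lists did not shift at 6 h. Both with limma-voom and without the low-count filter, however, camera called mitochondrially encoded genes (adjusted p = 1.34e-05 and 1e-06), ribosomal proteins (0.000633 and 5.9e-06), housekeeping genes (0.00384 and 0.000118) and glycolysis (0.00479 and 0.000351) up. Cholesterol synthesis (0.0196 and 0.0163) and nucleoside transport (0.0423 and 0.0207) were called down in both. Without the filter nuclear oxidative phosphorylation (0.0114) and NF-kB targets (0.00405) were also called up, the latter also in the deposited table with a pseudocount of 0.1 (0.0377). With library size only the medians of 9 of them turned negative, each keeping its sign relative to the median of all genes. These were the following 9 lists, with counts under TMM. Deoxynucleotide synthesis numbered 5 higher, 4 lower and 24 not passed, and G1/S and replication 10 higher, 8 lower and 24 not passed. The p53 targets numbered 7 higher, 7 lower and 6 not passed. Glycolysis numbered 14 higher, 4 lower and 6 not passed (16 and 4 adjusted over the list alone), and nuclear oxidative phosphorylation 6 higher, 0 lower and 24 not passed (3 higher adjusted over the list alone). Ribosomal proteins numbered 15 higher, 0 lower and 29 not passed (17 higher adjusted over the list alone). Transition and matrix genes numbered 5 higher, 2 lower and 8 not passed. Ductal markers numbered 6 higher, 5 lower and 9 not passed (7 higher adjusted over the list alone), and housekeeping genes 11 higher, 0 lower and 11 not passed (12 higher adjusted over the list alone). In the deposited normalized values 5 other medians turned positive, again with the sign relative to all genes kept. Of these, G2/M and mitosis numbered 4 higher, 9 lower and 21 not passed (10 lower adjusted over the list alone), and cholesterol synthesis 2 higher, 10 lower and 13 not passed. Hypoxia genes numbered 3 higher, 4 lower and 12 not passed, ATF4 targets 4 higher, 6 lower and 10 not passed and immediate early genes 9 higher, 6 lower and 12 not passed. Turned in neither, nucleoside transport numbered 0 higher, 4 lower and 3 not passed, NF-kB targets 7 higher, 2 lower and 9 not passed and mitochondrially encoded genes 13 higher, 0 lower and 0 not passed. BUB1, a spindle checkpoint kinase, rose by 0.54 (SE 0.035), CDC25B, a phosphatase of mitotic entry, stood at 0.065 (SE 0.029) and was called lower with library size only at -0.075. Without 6 h library 3 CDC25B was called higher at 0.079 (adjusted p = 0.043). INSIG1, a regulator of cholesterol synthesis, fell with -0.67 (SE 0.14). CDKN1A, the cell cycle inhibitor p21, rose by 0.52 (SE 0.045), and MKI67, the proliferation marker, stood at 0.024 (SE 0.057). Median and test differed in sign for ductal markers and G1/S genes (medians 0.12 and 0.02, test down) and immediate early genes (-0.02, test up), and mean and test for p53 targets (-0.03, up) and hypoxia (mean 0.03, down). Of marker genes of leukocytes, 3 of 14 were tested, with 2 higher and 1 not passed, among them CD68 at 1.87 (SE 0.041) and LYZ at 0.19 (SE 0.034), a list too small for camera that was called up without the low-count filter (7 genes, adjusted p = 0.0343), and of fibroblast, endothelial and acinar markers 3 of 17, with 1 higher and 2 not passed.

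The second comparison, 24 h against control, asks what held or appeared later. The controls have no stated time, so changes against control may include effects of time in culture or since the medium change. The antiviral response was still high. IFI44L, an interferon-induced gene, MX1 and IFI6, an inhibitor of apoptosis, were among the largest rises, with log2 fold changes of 6.53 (SE 0.10), 6.26 (SE 0.088) and 6.08 (SE 0.087) (n = 3 per group), and IFI6 went from 9.47 ± 0.761 to 637 ± 20.4 CPM. HCP5, a noncoding RNA in the HLA region (chromosome 6, 31463170 to 31478936), rose 32.6-fold to 20.3 ± 0.719 CPM. Genes that fell included TNC, the matrix protein tenascin C, with -2.69 (SE 0.11), and TMEM158, a gene induced by RAS signalling, with -2.68 (SE 0.075). By edgeR the adjusted p was 7.35e-14 for HCP5 and 1.45e-11 for TNC, each with all 3 treated libraries on one side of all 3 controls.

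Of 59 antiviral genes, 58 were higher, 0 were lower and 1 did not pass at 24 h, with a median of 2.87 (0.000493 as the adjusted p of camera with an estimated correlation). Interferon signalling genes numbered 13 higher, 2 lower and 6 not passed, with STAT2 at 2.07 (SE 0.063), IRF9 at 2.40 (SE 0.066) and USP18 at 4.05 (SE 0.049), whereas SOCS1 stood at -0.36 (SE 0.36). IFNAR2 was higher with 0.33 (SE 0.049) and IFNAR1 did not pass at 0.024 (SE 0.041), although it was called higher with library size only (0.102, adjusted p = 0.0483) and in the deposited normalized table (0.457, 0.0141). Nucleic acid sensing numbered 16 higher, 3 lower and 0 not passed. STING1 rose by 1.17 (SE 0.048). CGAS fell, with -0.37 (SE 0.073), though it stood at 0.068 in the deposited normalized table, in which the median of all genes at 24 h was 0.371, against 0.005 with TMM. Class I genes numbered 21 higher, 0 lower and 1 not passed, with HLA-B at 4.03 (SE 0.039). Class II genes numbered 8 higher, 0 lower and 0 not passed, with HLA-DMB, CD74 and HLA-DRA, an antigen-presenting chain, at 2.39 (SE 0.044), 2.28 (SE 0.049) and 2.26 (SE 0.14). Checkpoint ligands numbered 6 higher, 3 lower and 1 not passed (6 higher and 4 lower adjusted over the list alone): CD274 rose by 2.96 (SE 0.35), or 3.97 without control library 2, and NT5E fell, with -0.77 (SE 0.034). The list passed camera at adjusted p = 0.000352, but not with limma-voom (adjusted p = 0.3), without the low-count filter (0.143) or in the deposited table with a pseudocount of 0.1 (0.0831). Cell death genes numbered 20 higher, 7 lower and 5 not passed (22 higher adjusted over the list alone), a list call that was lost at adjusted p = 0.073 with an estimated correlation. NAD and PARP genes numbered 16 higher, 4 lower and 9 not passed (18 higher adjusted over the list alone). Chemokine and cytokine genes numbered 11 higher, 1 lower and 0 not passed and did not shift as a list, although camera called them up with limma-voom (adjusted p = 0.00822), without the low-count filter (0.00264) and in the deposited table with a pseudocount of 0.1 (0.000372). CXCL10 had a ratio of 5.18 (counting interval 1.62 to 26.4) and CXCL11 of 6.31 (1.58 to 54.9). The call of CXCL11 was lost without control library 1 (2.01, adjusted p = 0.0792), control library 2 (2.79, 0.0519) or 24 h library 1 (2.28, 0.0595), with DESeq2 (2.68, 0.0503) or in the deposited table with a pseudocount of 1 (0.32, 0.0592). IDO1 had 13 counts at 24 h against 1, a ratio of 6.31 whose counting interval of 0.948 to 268 includes no change. Its edgeR call (adjusted p = 0.0432) was lost without control library 1 (0.151), control library 2 (0.189), 24 h library 2 (0.0745) or 24 h library 3 (0.0769). Without control library 3 its fitted log2 fold change moved to 4.76, and that of CXCL10 to 3.08 without control library 2.

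Genes of DNA replication and mitosis moved apart at 24 h. Of 42 G1/S and replication genes, 37 were higher, 2 were lower and 3 did not pass (median 0.47), with CCNE2, a cyclin of S phase entry, at 1.14 (SE 0.072), PRIM1, the primase subunit, at 0.95 (SE 0.047) and the transcription factor E2F2 at 0.99 (SE 0.079). These named genes all rose, whereas the lowest log2 fold change on the list was -0.83. PRIM1 overlaps NACA, AC117378.1 and HSD17B6, and CCNE2 overlaps INTS8 and NDUFAF6 on the annotation. Of 34 G2/M and mitosis genes, 0 were higher, 33 were lower and 1 did not pass (34 lower adjusted over the list alone; median -0.49). PLK1, a mitotic kinase, stood at -1.06 (SE 0.031), CDC20, the activator of the anaphase-promoting complex, at -1.02 (SE 0.034), and BUB1 at -0.48 (SE 0.035). MKI67 fell, with -0.47 (SE 0.057), and CDKN1A fell, with -1.19 (SE 0.048). Of 25 cholesterol synthesis genes, 18 were higher, 1 was lower and 6 did not pass, with INSIG1 at 3.09 (SE 0.090) and IDI1, an isoprenoid isomerase, at 1.11 (SE 0.044). Immediate early genes numbered 4 higher, 18 lower and 5 not passed (19 lower adjusted over the list alone), with a median of -0.34 that was 0.086 in the deposited normalized table. FOSL1, an AP-1 subunit, fell with -1.76 (SE 0.028) and DUSP4, a MAP kinase phosphatase, with -1.18 (SE 0.034), whereas EGR1, a zinc finger factor, rose by 1.78 (SE 0.092). Transition and matrix genes numbered 3 higher, 8 lower and 4 not passed, with a median of -0.29 that was 0.077 in that table, and included MMP1, a collagenase, with -1.57 (SE 0.026), and SNAI2, a transition factor, with -1.68 (SE 0.084). Of 44 ribosomal protein genes, 1 was higher, 33 were lower and 10 did not pass, with a median of -0.15 that was 0.29 in that table. The list call was lost at adjusted p = 0.526 with an estimated correlation and at 0.157 in that table. RPLP0 and RPS6 stood at -0.48 (SE 0.028) and -0.42 (SE 0.023).

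TYMP remained raised at 24 h, at 77.1 ± 2.16 CPM and 3.45 (SE 0.061) on the log2 scale. Of the 13 thymidine and pyrimidine breakdown genes, 5 were higher, 6 lower and 2 not passed, with a median of -0.19 against a camera shift upwards at adjusted p = 0.00786. The median was 0.242 in the deposited normalized table. Camera did not pass with limma-voom (adjusted p = 0.914, direction down), without the low-count filter (0.874) or in that table with a pseudocount of 0.1 (0.85). CDA fell, with -0.83 (SE 0.058), as did UPP1, with -0.29 (SE 0.033). CMPK2 was higher with 5.85 (SE 0.11) and SAMHD1 6.50-fold, at 344 ± 8.10 CPM. TK1 did not pass at 0.051 (SE 0.047) (adjusted p = 0.398 by edgeR), nor did DCK at 0.10 (SE 0.060), though both were called higher with library size only, at 0.128 and 0.173, and in the deposited normalized table, at 0.484 (adjusted p = 0.00881) and 0.525 (0.00541). RRM2 rose by 0.38 (SE 0.026), and TYMS, DTYMK and SLC29A1 fell, with -0.23 (SE 0.028), -0.38 (SE 0.045) and -0.34 (SE 0.051), whereas in the deposited normalized table TYMS, DTYMK, SLC29A1 and UPP1 stood at 0.208, 0.059, 0.091 and 0.151, none of them called. SLC29A2 was higher with 0.26 (SE 0.057) and SLC29A3 with 0.49 (SE 0.14), the latter not past the threshold without control library 2 (0.34, adjusted p = 0.0507).

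By edgeR's test 8475 genes passed at 24 h, 4191 higher and 4284 lower, of which 818 and 291 changed at least 2-fold and 6010 changed by under 1.5-fold. Of the calls 49.5% were higher, against 64.1% with library size only and 96.4% in the deposited normalized table. In that table NT5E, MKI67, HK2, BUB1 and RPLP0 no longer passed at 24 h, nor did CDA and IDO1 with a pseudocount of 1 (adjusted p = 0.0531 and 0.33), though both passed with 0.1. RPS6 and SOCS1 turned to 0.017 and 0.029 there without passing. IDO1 also did not pass with DESeq2, without the low-count filter or after thinning. Camera called 15 lists, 11 up and 4 down, and 13 of them passed with an estimated correlation. In mixed splits of these libraries, which keep part of the real difference and in which 0 genes passed, it called 9 to 14 lists. The medians of 5 lists that did not shift changed sign under another scaling or after thinning. Deoxynucleotide synthesis numbered 7 higher, 10 lower and 16 not passed, with a median of -0.014 that was 0.064 with library size only and 0.423 in the deposited table. Mitochondrially encoded genes numbered 4 higher, 7 lower and 2 not passed, with 0.344 in the deposited table, and housekeeping genes 5 higher, 11 lower and 6 not passed, with 0.356 there. Glycolysis numbered 8 higher, 9 lower and 7 not passed, with -0.011 after thinning, and hypoxia 4 higher, 4 lower and 11 not passed, with -0.033 after thinning. Nucleoside transport numbered 2 higher, 2 lower and 3 not passed and NF-kB targets 9 higher, 6 lower and 3 not passed. The p53 targets numbered 7 higher, 8 lower and 5 not passed (9 and 8 adjusted over the list alone), and ATF4 targets 7 higher, 7 lower and 6 not passed (8 and 8 adjusted over the list alone). Amino acid catabolism numbered 4 higher, 0 lower and 5 not passed and nuclear oxidative phosphorylation 20 higher, 2 lower and 8 not passed. The latter was called up with limma-voom (adjusted p = 0.00102), with library size only (0.0161), without the low-count filter (6.61e-06) and in the deposited table with a pseudocount of 0.1 (0.0387). Ductal markers numbered 13 higher, 4 lower and 3 not passed (5 lower adjusted over the list alone) and were called up with limma-voom (0.0332) and without the filter (0.00661), and housekeeping genes were called down without the filter (0.0317). The amino acid catabolism median was 0.49, or 0.18 with its low members at the floor of 3 counts. Median and test differed in sign for thymidine breakdown and deoxynucleotide synthesis (-0.19 and -0.01, up), and for nucleoside transport, p53 targets, glycolysis and ATF4 targets (0.07, 0.12, 0.009 and 0.04, down). All 3 tested leukocyte markers were higher, with CD68 at 1.38 (SE 0.041) and LYZ at 0.54 (SE 0.033), and the list was called up without the filter (7 genes, adjusted p = 0.00737). Of 3 tested fibroblast, endothelial and acinar markers 1 was higher and 2 did not pass. The 1 interferon gene tested did not pass.

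**Figure D2:**
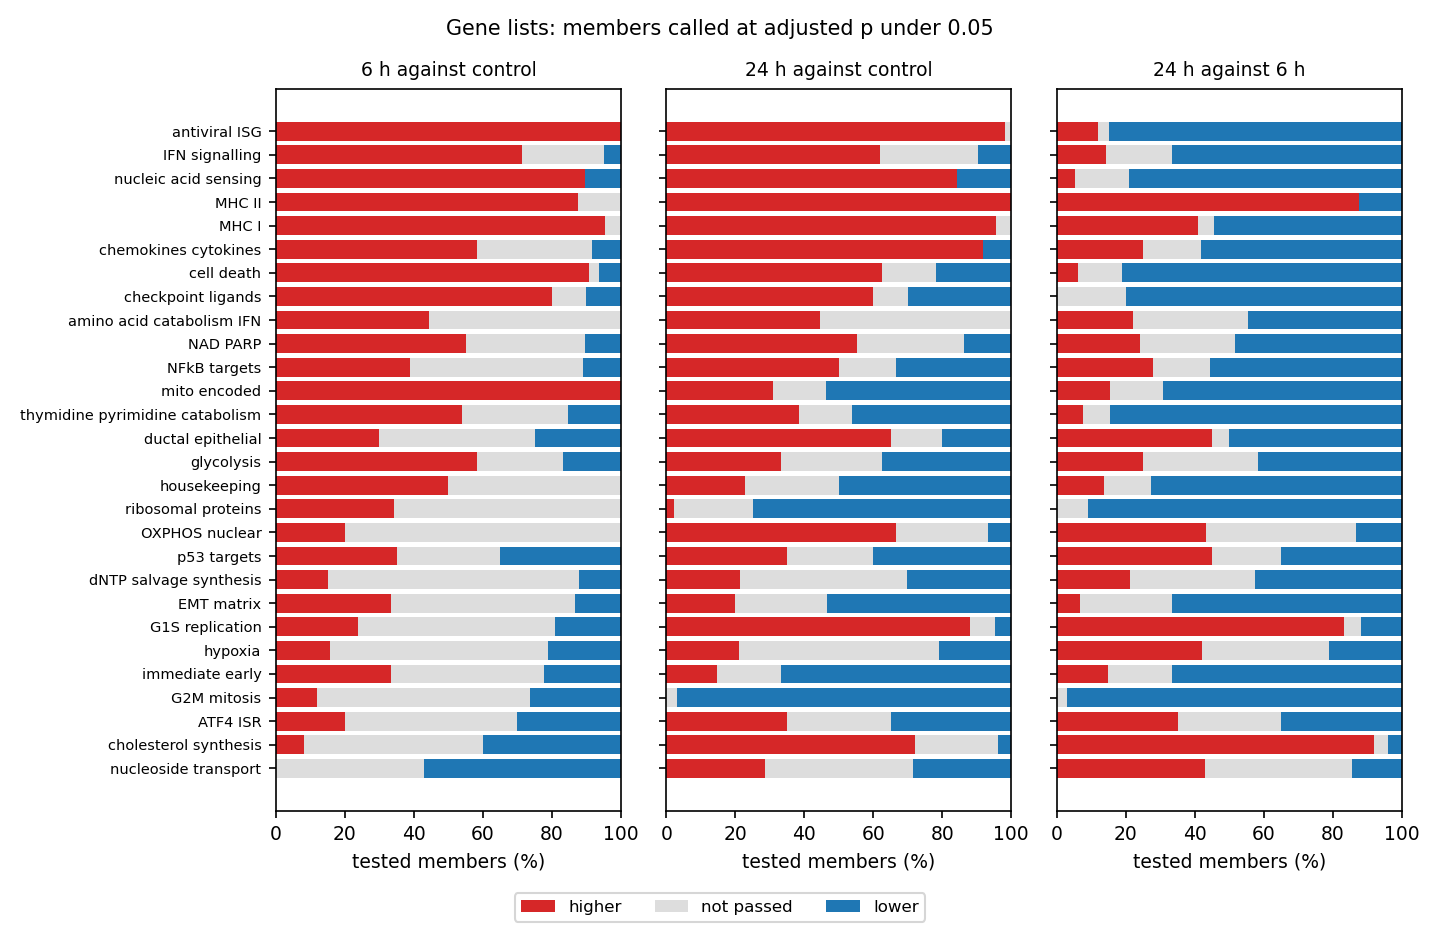
Share of tested members (percent) of each of 28 gene lists that were higher, lower or not passed in each of the 3 comparisons, by edgeR at adjusted p under 0.05 with TMM scaling. All 59 antiviral genes were higher at 6 h and 58 at 24 h; shares of lists with small changes depend on the scaling, and with library size only the medians of 10 lists at 6 h turned sign.

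The third comparison, 24 h against 6 h, tests whether the 2 exposed groups differed. Both were set against the same controls, which have no stated time. A difference in the effect of interferon thus cannot be set apart from time in culture or since the medium change. Most antiviral transcripts were lower at 24 h than at 6 h, and most class II, replication and cholesterol genes were higher. GBP4 fell from 337 ± 18.4 to 14.3 ± 0.542 CPM (SD, n = 3 per group), with -4.56 (SE 0.055), RSAD2 fell with -3.44 (SE 0.056), SOCS1 with -4.30 (SE 0.21) and CD274 with -3.64 (SE 0.14). In the other direction HCP5 rose with 4.17 (SE 0.11), INSIG1 with 3.76 (SE 0.092) and HLA-DMB with 2.37 (SE 0.042). By edgeR the adjusted p was 2.31e-17 for GBP4 and 8.05e-16 for HLA-DMB, each with all 3 libraries of one time above all 3 of the other.

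Of 59 antiviral genes, 7 were higher, 50 were lower and 2 did not pass at 24 h relative to 6 h (median -1.48); IFI6 was among those higher, with 0.80 (SE 0.059). Interferon signalling numbered 3 higher, 14 lower and 4 not passed and nucleic acid sensing 1 higher, 15 lower and 3 not passed. Chemokines numbered 3 higher, 7 lower and 2 not passed, checkpoint ligands 0 higher, 8 lower and 2 not passed and cell death genes 2 higher, 26 lower and 4 not passed. Class I genes numbered 9 higher, 12 lower and 1 not passed, with a median of -0.20 that was 0.018 with library size only and 0.074 in the deposited table. The median of all genes was 0.198 and 0.215 under these scalings, against -0.019 with TMM. The call ended with limma-voom (adjusted p = 0.132). NAD and PARP genes numbered 7 higher, 14 lower and 8 not passed, with a median of -0.13 that was 0.086 and 0.12 there, and the call ended with limma-voom (0.0823). Amino acid catabolism numbered 2 higher, 4 lower and 3 not passed, with a median of -0.08 that was 0.14 and 0.188 there, and the call ended with limma-voom (0.29). Thymidine breakdown genes numbered 1 higher, 11 lower and 1 not passed, with TYMP at -1.02 (SE 0.037). TK1 did not differ detectably, with -0.0046 (adjusted p = 0.942 by edgeR), although it was 0.213 and called with library size only and -0.077 (adjusted p = 0.0487) without 6 h library 3. DCK did not pass at 0.13 (SE 0.057), but was 0.225 (adjusted p = 0.00068) without that library and was called in 8 further settings. The fall of UPP1, at -0.10 (SE 0.032), turned to 0.112 with library size only, a called rise, and did not pass with DESeq2, with 2 groups only or after thinning. Class II genes numbered 7 higher, 1 lower and 0 not passed, G1/S and replication 35 higher, 5 lower and 2 not passed and cholesterol synthesis 23 higher, 1 lower and 1 not passed. G2/M and mitosis genes numbered 0 higher, 33 lower and 1 not passed, immediate early genes 4 higher, 18 lower and 5 not passed and transition and matrix genes 1 higher, 10 lower and 4 not passed. Ribosomal proteins numbered 0 higher, 40 lower and 4 not passed, with a median of -0.25 that was 0.027 in the deposited table. Housekeeping genes numbered 3 higher, 16 lower and 3 not passed, with a median of -0.18 that was 0.036 with library size only and 0.092 in the deposited table. ACTB, cytoskeletal actin, stood at -0.81 (SE 0.020). Both calls were lost with an estimated correlation, at adjusted p = 0.434 with an estimated correlation for ribosomal proteins and 0.0748 for housekeeping genes, and the housekeeping call also ended with library size only (0.389) and in the deposited table (0.262).

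By edgeR's test 9704 genes differed between the times, 4520 higher and 5184 lower at 24 h. Of these 1432 differed by at least 2-fold, 826 of them higher, and 6511 by under 1.5-fold. Of the calls 46.6% were higher, against 76.9% with library size only and 83.3% in the deposited table. In that table IRF9, IFI44L, MKI67, CDA, RPLP0, RPS6 and CD68 no longer passed, nor did STING1 with a pseudocount of 0.1. LGALS9, TYMS, SLC29A1, DTYMK and UPP1 changed sign there without passing. With library size only LGALS9, TYMS and SLC29A1 did not pass, and DTYMK changed sign without passing. Camera called 18 lists, 3 up and 15 down, and 16 passed with an estimated correlation. In mixed splits of these libraries, which keep part of the real difference and in which 0 genes passed, it called 8 to 13 lists. Counts adjusted over the list alone were the same except for nuclear oxidative phosphorylation. The other 10 lists did not shift. Of them, nuclear oxidative phosphorylation was called up with limma-voom (adjusted p = 0.0459), with library size only (0.00352) and without the low-count filter (0.0414). Mitochondrially encoded genes were called down with limma-voom (0.00863) and without the filter (0.000624), and glycolysis down without the filter (0.0262) and without 6 h library 3 (0.0373). The medians of 5 of the 10 turned positive with library size only and in the deposited table. Of these, deoxynucleotide synthesis numbered 7 higher, 14 lower and 12 not passed and NF-kB targets 5 higher, 10 lower and 3 not passed. Glycolysis numbered 6 higher, 10 lower and 8 not passed, ATF4 targets 7 higher, 7 lower and 6 not passed and ductal markers 9 higher, 10 lower and 1 not passed. Mitochondrially encoded genes, whose median turned in the deposited table alone, numbered 2 higher, 9 lower and 2 not passed. Nucleoside transport numbered 3 higher, 1 lower and 3 not passed, p53 targets 9 higher, 7 lower and 4 not passed and hypoxia 8 higher, 4 lower and 7 not passed. Nuclear oxidative phosphorylation numbered 13 higher, 4 lower and 13 not passed (14 higher adjusted over the list alone). Median and test differed in sign for p53 targets (0.09, down) and ductal markers (-0.17, up). Of 3 leukocyte markers 2 were higher and 1, CD68 at -0.49 (SE 0.034), lower, of 3 fibroblast, endothelial and acinar markers 1 was lower and 2 did not pass, and the 1 interferon gene tested was lower.

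Of the 636 genes at least 2-fold higher at 6 h, 493 were lower at 24 h than at 6 h, 103 did not differ by the test and 40 were higher, and 493 were still called higher than control. Their median log2 fold change was 1.93 at 6 h and 1.105 at 24 h. Of the 818 genes at least 2-fold higher at 24 h, 484 were higher at 24 h than at 6 h, 130 did not differ by the test and 204 were lower, and 359 were also called higher at 6 h. Their median log2 fold change was 0.519 at 6 h and 1.544 at 24 h. Each set was chosen by its change at one of the times. In all, 2429 genes changed in the same direction at both times, 1324 higher and 1105 lower, and 1244 in opposite directions, 661 higher then lower and 583 lower then higher. Independent lists of these sizes would share 1392 genes in the same direction and 1394 in opposite directions. Simulated unchanged groups set against the same controls gave a mean of 0.12 and at most 1 in the same direction. With no gene changed, few pass the adjusted threshold, so this low count was nearly fixed. It does not measure what the shared controls add to the real count. The log2 fold changes at the 2 times correlated across genes at 0.565, against 0.59 from the simulations, with a covariance of 0.244 against 0.0303; genes are not independent replicates. The 3 controls could not be split into parts of at least 2, so part of the excess may come from the shared controls. MLKL, the effector of necroptosis, rose at 6 h with 1.83 (SE 0.042) and fell at 24 h with -0.21 (SE 0.047), although it stood at 0.226 at 24 h in the deposited table, and HK2, a hexokinase, went from 1.18 (SE 0.038) to -0.49 (SE 0.040).

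**Figure D3:**
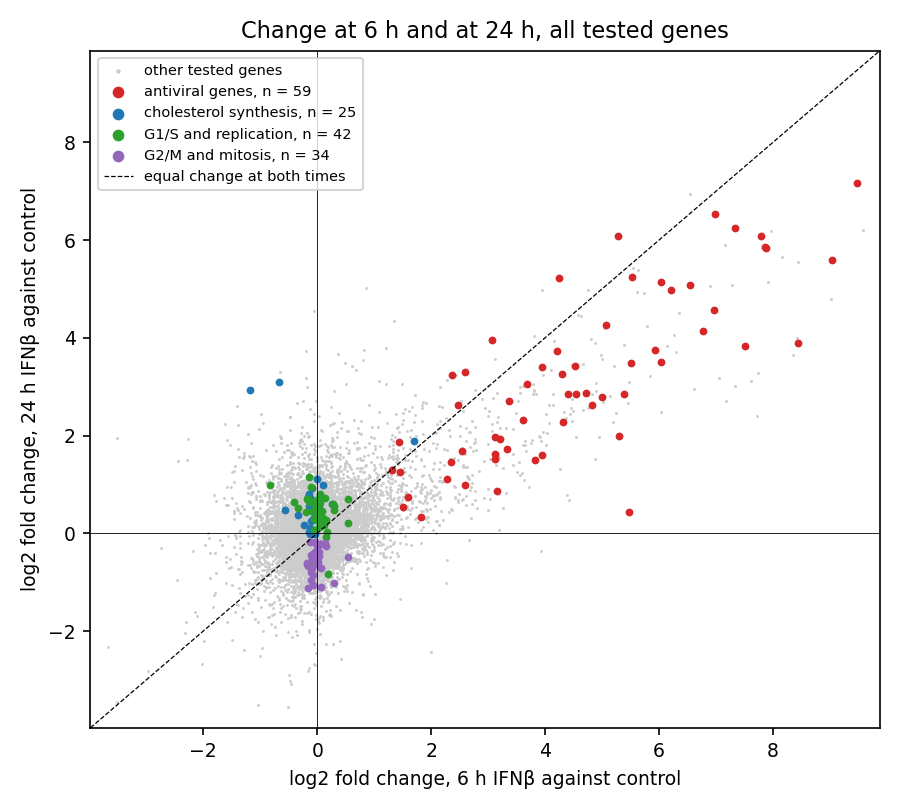
Log2 fold change at 24 h (vertical axis) against that at 6 h (horizontal axis), each against control, for each of 16964 tested genes, with the members of 4 gene lists in colour and a dashed line of equal change. The antiviral genes lie to the right of 0 with medians of 4.32 at 6 h and 2.87 at 24 h.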

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

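Apart from the comparison of 24 h against 6 h, the splits of the samples and the depth test of the deposited table, the tests below were chosen only after the results were seen. The 6 h and 24 h groups differed by the test of 24 h against 6 h for 9704 genes and 18 lists. An effect of exposure cannot be set apart there from time in culture. Against control, 661 genes were higher then lower and 583 lower then higher. Median log2 fold changes of 24 h against 6 h were -1.48 for antiviral genes, -0.69 for interferon signalling, -0.86 for nucleic acid sensing, -0.20 for MHC class I, 0.73 for MHC class II, -0.94 for chemokines, -0.64 for checkpoint ligands, -0.42 for thymidine breakdown, 0.40 for G1/S genes, -0.45 for G2/M genes, -0.90 for cell death, -0.13 for NAD and PARP, -0.077 for amino acid catabolism, 0.41 for cholesterol synthesis, -0.51 for immediate early genes, -0.25 for ribosomal proteins, -0.35 for transition and matrix genes and -0.18 for housekeeping genes. The signs of MHC class I, NAD and PARP, amino acid catabolism and housekeeping medians turned with library size only and in the deposited table, and that of ribosomal proteins in the deposited table. With an estimated correlation 16 lists passed, without ribosomal proteins and housekeeping genes.

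Among the genes named in the report that passed this test, the log2 fold change of 24 h against 6 h was positive for HCP5 4.17, INSIG1 3.76, HLA-DMB 2.37, EGR1 1.81, E2F2 1.81, CCNE2 1.29, IDI1 1.10, PRIM1 1.07, HLA-DRA 1.03, SLC29A3 0.99, ZMAT3 0.95 and IFI6 0.80. Smaller positive values were those of SLC29A2 0.65, CD74 0.58, CERK 0.54, RRM2 0.40, LYZ 0.36, IFNAR2 0.31, IFNAR1 0.23 and HLA-B 0.22. The most negative values among these named genes were those of IDO1 -5.33, GBP4 -4.56, SOCS1 -4.30, CD274 -3.64, RSAD2 -3.44, ETV7 -3.37, KMO -3.35, CXCL10 -2.91, APOL6 -2.78, TNC -2.66, DDX58 -2.64 and TMEM158 -2.63. Next came CSF1 -2.55, NLRC5 -2.37, PARP14 -2.35, TRIM22 -2.31, USP18 -2.20, IFIH1 -2.17, CXCL11 -2.15, NT5C3A -2.08, MLKL -2.04, CMPK2 -2.03, TAP1 -1.98 and MMP1 -1.97. These were followed by STAT2 -1.89, WARS1 -1.87, CIITA -1.84, FOSL1 -1.74, IFIT1 -1.72, CDKN1A -1.71, HK2 -1.67, DUSP4 -1.66, NT5E -1.33, CDC20 -1.31, XAF1 -1.24 and SNAI2 -1.21. Less negative values were those of CDC25B -1.16, CGAS -1.11, MX1 -1.08, BUB1 -1.02, TYMP -1.02, PLK1 -0.98, SAMHD1 -0.83, ACTB -0.81, STING1 -0.67, CDA -0.60, IRF9 -0.59 and RPLP0 -0.52. Also negative were CD68 -0.49, MKI67 -0.49, RPS6 -0.47, IFI44L -0.45, SLC29A1 -0.26, LGALS9 -0.25, TYMS -0.22, DTYMK -0.21 and UPP1 -0.10. In the deposited table IRF9, IFI44L, MKI67, CDA, RPLP0, RPS6 and CD68 no longer passed for this comparison, and LGALS9, TYMS, SLC29A1, DTYMK and UPP1 changed sign without passing. With library size only LGALS9, TYMS and SLC29A1 did not pass, DTYMK changed sign without passing and UPP1 was called higher.

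Of the 6 treated libraries, 5 had higher totals than each control library in the deposited normalized table, and the exception was 6 h library 1, whose implied factor of 1.18 lay above the 1.07 of control library 2. The implied factors spanned 1.549-fold, against 1.171-fold for the factors of tested genes. TMM factors recomputed over all genes with 0.0001 added matched those of the table within 0.07%, so the added constant over genes at 0, which were 42.6% of all, may account for the offset. Library depth cannot be set apart from the added constant. Factors recomputed in the same way spanned 1.55-fold, and 1.001-fold after thinning to equal depth. That outcome was nearly fixed, since at equal depth genes at 0 hold the same value in each library. The span of tested genes was also already small. No biological explanation was tested.

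Most replication genes were higher at 24 h (37 higher, 2 lower and 3 not passed) and most mitosis genes lower (33 lower and 1 not passed). The difference of the list medians was 0.96 on the log2 scale under each scaling of the counts. This was fixed in advance, since a factor per library moves both medians alike. Scaling thus cannot account for the difference, but it can move each median relative to 0. After thinning the difference was 0.977. Thinning keeps the expected ratios of counts, so this outcome was nearly fixed and cannot say whether depth played a part. Time in culture or since the medium change stays open, since 0 control libraries have a stated time. An effect of interferon on the cell cycle may contribute, as a hypothesis that these libraries cannot set apart from time.

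Of the 1244 genes called in opposite directions at the 2 times, 97.3% kept both calls with median-of-ratios scaling and 61.8% with library size only, so scaling stays open for part of them. Opposite calls numbered 1988 in all with library size only, 1234 with median-of-ratios scaling and 1047 after thinning. Of those changed at least 1.5-fold both times, 84 of 84 kept their calls under both scalings, a test added after the first was undecided and nearly fixed by the size of the changes. After thinning 78.7% of all and 67 of the 84 kept their calls. Thinning keeps the expected ratios and lowers the power of the test, so these shares cannot say whether depth was a cause. A change of response with time stays open, as a hypothesis.

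The 6 libraries of each comparison allow 10 splits, too few for a share under 0.05. The counts of genes were 5576, 8475 and 9704, with 0 as the highest of the other splits in each (1 split as large, the real one), and the counts of lists were 11, 15 and 18, with 11, 14 and 13 as the highest others (2, 1 and 1 as large). A count of lists thus hardly sets the real groups apart from mixed ones in the comparisons with control. Mixed splits hold unequal numbers of both groups, however, and so keep part of the real difference, which can itself shift lists. They also widen the spread within groups, which lowers the count of genes. Neither count is therefore a measure of false calls. For genes changed in the same direction at both times, 1 of 100 drawn splits was as large as the real 2429, the real one itself. The highest other was 1447, so random groupings of these libraries rarely gave such a count. Chance between cultures cannot be excluded this way, since the labels do not say that replicates were separate cultures. The count also depends on which group serves as the control.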

How the results depend on the processing

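Thinning was the only alternative chosen after the depths were seen. Over 237 gene values and 20 settings, 4524 values kept direction and side of the threshold, 74 no longer passed, 35 came to pass and 90 reversed; 171 gene values were the same in all settings, and the low genes CXCL11 and KMO had no value with at least 1 CPM or thinning, nor these, CXCL10, IDO1 and SOCS1 at 24 h with 2 groups only, where they were not tested. With each library left out, genes changed ranged from 4722 to 5489 at 6 h, 7497 to 8981 at 24 h and 8847 to 9739 between times, those in the same direction from 2023 to 2478, and at least 2-fold from 753 to 798, 1080 to 1189 and 1425 to 1518; lists stayed at 11 and 15 and ranged from 18 to 19. DESeq2 called 4500, 7084 and 8210 genes, and thinned counts 5071, 7709 and 8569. With the replicate number as a block the counts were 5149, 8133 and 9393, and the block changed the call of no named gene. Deviations of libraries with the same number correlated from -0.0588 to 0.0214, against -0.0277 to 0.0712 for other numbers. No shared effect of the number was detected, and whether the numbers pair the samples is unknown. Lists shifted at 6 h rose to 17 with limma-voom and 20 without the low-count filter. Genes in the same direction fell to 1617 at an adjusted p under 0.01. In the deposited table with a pseudocount of 1, the counts were 1826 at 6 h, 5849 between times, 776 of at least 2-fold between times and 1249 in the same direction; with 0.1 they were 1854, 5636, 1975 of at least 2-fold at 24 h and 1282. With library size only the log2 fold change of 363, 4 and 1234 called genes changed sign. In the deposited table with a pseudocount of 1 that of 399, 2891 and 1883 did. These genes were counted whether or not they passed under the other scaling. Low depth limits CXCL10, CXCL11, IDO1 and KMO, with 3 or fewer control counts.

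The deposited table and library size only shift all genes together, with medians of 0.134, 0.371 and 0.215 in the former and -0.145, 0.082 and 0.198 in the latter. Relative to all genes, 0 list medians turned with library size only, and 0, 1 and 2 in the deposited table. For the other changes the cause was not tested. Reversed log2 fold changes in the deposited table with a pseudocount of 1 were at 6 h TYMS 0.155, DTYMK 0.001, DCK 0.109, RRM2 0.146, SLC29A1 0.089, PLK1 0.085, CCNE2 0.036, PRIM1 0.034, TNC 0.126, TMEM158 0.114, FOSL1 0.145 and EGR1 0.106, at 24 h SOCS1 0.029, CGAS 0.068, MLKL 0.226, UPP1 0.151, TYMS 0.208, DTYMK 0.059, SLC29A1 0.091 and RPS6 0.017 and for 24 h against 6 h LGALS9 0.019, UPP1 0.166, TK1 0.26, TYMS 0.053, DTYMK 0.058 and SLC29A1 0.002. With a pseudocount of 0.1 they were at 6 h TYMS 0.156, DTYMK 0.001, DCK 0.111, RRM2 0.146, SLC29A1 0.09, PLK1 0.085, CCNE2 0.039, PRIM1 0.034, TNC 0.134, TMEM158 0.117, FOSL1 0.145 and EGR1 0.124, at 24 h SOCS1 0.095, CGAS 0.071, MLKL 0.233, UPP1 0.153, TYMS 0.209, DTYMK 0.06, SLC29A1 0.093 and RPS6 0.017 and for 24 h against 6 h LGALS9 0.019, UPP1 0.169, TK1 0.262, TYMS 0.053, DTYMK 0.059 and SLC29A1 0.002. With library size only they were at 6 h HLA-DMB -0.114, TK1 -0.084, IFNAR2 -0.111, MKI67 -0.116, CDC25B -0.075, IDI1 -0.135, RPLP0 -0.105, RPS6 -0.088 and ACTB -0.048 and for 24 h against 6 h UPP1 0.112, TK1 0.213 and DTYMK 0.01. TK1 for 24 h against 6 h turned to 0.003 with DESeq2, 0.007 with limma-voom, 0.005 with median-of-ratios scaling, 0.004 with at least 1 CPM and 0.018 with 2 groups only, and TYMS at 6 h to 0.009 without the filter. Thinning reversed at 6 h HLA-DMB -0.017, IDI1 -0.005 and EGR1 0.18. With each library left out, the following signs turned. SOCS1, 24 h against control, ranged from -0.554 to 0.007. HLA-DMB, 6 h against control, ranged from -0.018 to 0.062. TK1, 24 h against 6 h, ranged from -0.077 to 0.034. TYMS, 6 h against control, ranged from -0.016 to 0.007. DCK, 6 h against control, ranged from -0.132 to 0.017. IFNAR1, 24 h against control, ranged from -0.002 to 0.047. IFNAR2, 6 h against control, ranged from 0 to 0.057. MKI67, 6 h against control, ranged from -0.056 to 0.09. IDI1, 6 h against control, ranged from -0.018 to 0.031. TNC, 6 h against control, ranged from -0.089 to 0.045. TMEM158, 6 h against control, ranged from -0.111 to 0.006.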

Other observations

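Single libraries stood apart in a few transcripts, chosen after their values were seen. The haemoglobin gene HBB had 9.65 CPM in control library 1 and at most 0.81 CPM in each of the others. In 24 h library 1, 5_8S_rRNA had 28.4 CPM, RMRP 19.1 CPM and RPPH1 7.46 CPM. Control library 3 had 2.41 CPM of CMPK2 against 1.06 and 1.08 in the other controls, and 1.70 CPM of RSAD2 against 0.78 and 0.86. Mitochondrial ribosomal RNA took 1.72 ± 0.026% of counts in control, 1.71 ± 0.118% at 6 h and 1.08 ± 0.06% at 24 h (SD, n = 3).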
